A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

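Total RNA of 12 rice leaf samples was labelled with biotin and hybridised to an Affymetrix rice array, per the labels' protocols. The groups and replicate numbers come from the sample titles, and the labels name 3 independent over-expression lines and 3 wild-type plants, so replicates are separate plants. The over-expression plants had been selected on hygromycin, and miR156 over-expression had been checked on RNA gel blots, per the labels' protocols; miR156 itself was not analysed here.

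The deposited table holds 1 linear signal intensity per probe set and array, for 57381 probe sets. The scanner, summarization and scaling are not given in the sources used here. The unit was read from the values, which are never negative and skewed, and the log2 medians of the arrays differed by at most 0.153, so no further normalization was applied. A scaling by the submitters that assumes equal totals would hide a change of all transcripts at once.

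In R 4.3.3, intensities were taken as log2(value + 16). The 187 array control probe sets and those with a mean under the 40th percentile were left out, which kept 34316. One limma 3.58.1 model (lmFit, and eBayes with a trend) over the 4 groups shared the spread with 8 residual degrees of freedom. The contrasts were OE against WT in each leaf, L6 against L3 in each genotype, and the difference of these leaf differences (the interaction). Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 joined names and drew figures.

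Gene names came from the platform annotation through gene IDs and the NCBI gene table of assembly ASM3414082v1, used only for names. The annotation gives 1 gene for 22436 probe sets and several for 95, and does not list 34850, which are unnamed here. All 22436 gene IDs were found in the table. They stand for 17905 genes, of which 2457 have a name other than a LOC number. Probe sets with several genes were not named.

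Before the data were examined, the comparisons, tests, alternatives, 41 gene lists and the rule for named genes were fixed. The rule takes, per comparison, the 6 highest and 6 lowest differences among called probe sets whose groups do not overlap and that name 1 gene, with 1 probe set per gene; the 2 members with the strongest statistic of each list that camera called; and every measured SPL gene in the over-expression comparisons. The rule asked for a gene with a description; the table holds none, so a name other than a LOC number was required. For the same reason the lists, written as gene IDs and description terms, were filled by gene symbols and synonyms. That was done after the numbers of called probe sets had been seen and before any list was compared. Lists with at least 4 measured genes were tested, 34 of 41, with 1 probe set per gene (the brightest, 15517 genes as background).

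The list test was camera with a preset correlation of 0.01, adjusted over 170 tests of lists by comparisons. It called 25, and 0 with an estimated correlation. Fry was run beside it.

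The pairing of L3 with L6 comes from the labels, which give both the same line or plant. Deviations from the group means of the same plant's leaves correlated at -0.24, -0.36 and -0.05 in WT and at 0.10, 0.14 and 0.20 in OE.

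The leaf-age score projects an array on the L6 minus L3 difference of the other genotype. The size of the leaf difference was compared with an exact permutation of the 6 plants. For comparisons that share WT arrays, 1000 draws with residuals of the arrays gave the values without effects.

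The fit was tested on simulated data, with 34316 probe sets of which 200 were changed in each comparison. Of the 2-fold changes, 80% were recovered in each of the 4 pairwise comparisons and 56% in the interaction. Of the 16-fold changes, 100% were recovered for OE against WT in L3, 98% in L6, 96% between leaves of WT, 98% between leaves of OE and 88% in the interaction. False calls numbered 9, 5, 10, 14 and 9. The simulated values were independent between probe sets, and each probe set had the same spread in all 4 groups. The real arrays were spread more widely in L3 than in L6, so these rates may not hold for them.

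Alternatives were quantile normalization, pseudocounts of 1 and 64, no filter, a 60th percentile filter, no trend, the replicate number or plant as a block, the plant as a random block, only the groups compared, 1 probe set per gene, a 2-fold minimum, an estimated correlation, and each replicate left out. The leaf-age score as a covariate was chosen after seeing the data.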

Results

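Transcript levels were measured in 12 leaf samples of rice (Oryza sativa, Japonica group) on an Affymetrix array, which reads each transcript with a set of short probes and gives 1 signal per probe set. Per the labels, 3 wild-type plants (WT) and 3 independent transgenic lines that over-express the microRNA miR156 (OE) were sampled at 45 days. In order of replicate number the OE lines were Md15, Md43 and Mh9. What sets an OE replicate apart thus cannot be told from a difference between lines. From each plant came an old leaf, leaf 3 (L3), and a young leaf, leaf 6 (L6), numbered in order of emergence on the main tiller. Leaf age and leaf position changed together between L3 and L6, so they cannot be told apart. Leaf age below stands for both. The 4 groups WT_L3, WT_L6, OE_L3 and OE_L6 thus held 3 arrays each, and the number of arrays limits the precision. MiR156 is a small RNA of the juvenile phase in plants that silences many SPL transcription factor genes by pairing with a site in their transcripts. The series asks which genes change, directly or indirectly, with extra miR156. No transgenic line without miR156 over-expression was sampled. Changes with over-expression thus cannot be told apart from those of transformation and selection on hygromycin. Levels are given as linear signal, mean ± SD with n = 3, and folds come from differences on the log2(signal + 16) scale, which understates the change of dim probe sets.

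The median signal of the arrays ran from 50.8 to 56.5. Pearson correlations across probe sets, which are not independent replicates, were 0.900 to 0.993 between arrays of 1 group and 0.721 to 0.942 between an L3 and an L6 array. The first principal component held 80.9% of the variance. A leaf-age score placed every array between the mean L3 (0) and the mean L6 (1) of the other genotype. L6 arrays scored 0.878 to 1.11. The L3 arrays were spread more widely, at 0.382, -0.286 and -0.266 in WT replicates 1 to 3 and at 0.254, 0.211 and -0.223 in OE replicates 1 to 3. The mean variance within a group was 0.169 in WT_L3 and 0.115 in OE_L3, against 0.0425 in WT_L6 and 0.0469 in OE_L6. The model pooled these variances. Its standard errors and p-values are therefore on average too small for OE against WT in L3 and too large for it in L6. OE_L6 replicate 1 differed from the other arrays in its controls: the log2 ratio of 3′ to 5′ signal of the Dap control was 5.35, and the 18S ribosomal RNA signal was 225.

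**Figure D1:**
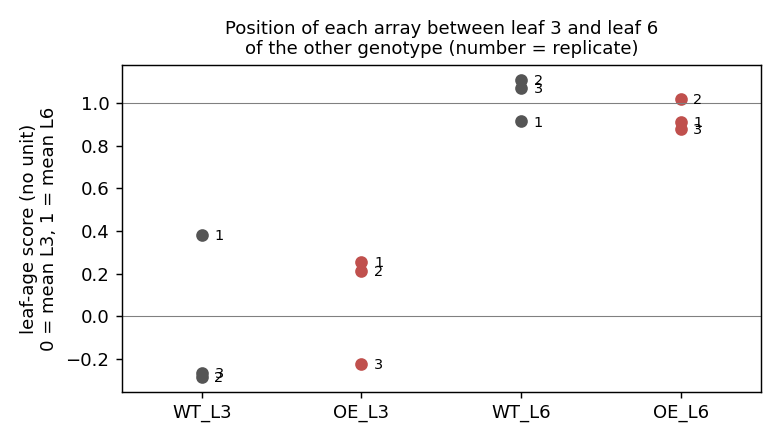
Leaf-age score (no unit, vertical axis) of each of the 12 arrays, by group, with 0 the mean L3 and 1 the mean L6 of the other genotype and the replicate number beside each point. The L6 arrays lie between 0.878 and 1.11, and the L3 arrays between -0.286 and 0.382.

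In old leaves, the named genes that changed with miR156 over-expression all fell. MT1B (LOC4332487), a metallothionein that binds metals, was at 149 ± 49.0 in OE_L3 and 759 ± 154 in WT_L3, a 4.78-fold difference (log2 difference -2.26, SE 0.20, limma adjusted p = 0.00095). NAR2.2 (LOC4336175), from a family of partner proteins of nitrate transporters, was at 151 ± 24.6 against 406 ± 23.1 (log2 -1.35, SE 0.10, adjusted p = 0.000421). SPL4 (LOC4328461), a miR156 target, was at 45.8 ± 4.46 against 86.4 ± 5.67 on its _at probe set (log2 -0.73, SE 0.08, adjusted p = 0.0068). NMCP1A (LOC4330487), a nuclear matrix constituent protein, was at 239 ± 18.3 against 376 ± 29.8 (log2 -0.62, SE 0.09, adjusted p = 0.0261). In each of these 4 genes all 3 OE arrays lay below all 3 WT arrays, which the rule for named genes required. A second SPL4 probe set, of a type (_x_at) that can also bind related transcripts, was at 186 ± 18.8 against 262 ± 20.5 and did not pass (log2 -0.46, adjusted p = 0.258). A further SPL4 probe set had a log2 difference of -0.12, and 2 further probe sets of NMCP1A had -0.08 and -0.15, without passing.

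Of the 34316 probe sets tested in L3, 41 changed, 29 higher and 12 lower in OE, and 1326 had an unadjusted p under 0.05. The 1326 are fewer than the share of 0.05 that chance gives on average. All 41 had groups that did not overlap, as did 8.54% of all probe sets, where chance gives 10%. The 4 named genes lost their calls when the 2 groups were fitted alone (adjusted p 0.172 for MT1B, 0.0984 for NAR2.2, 0.196 for SPL4 and 0.505 for NMCP1A), and the count was then 12. Without OE_L3 replicate 1 the count was 25, without OE_L3 replicate 2 or WT_L3 replicate 2 it was 22, and the call of NMCP1A was lost without any 1 of the 6 L3 arrays (adjusted p 0.0582 to 0.113).

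Among gene groups in L3, camera called the SPL genes with a miR156 site as lower in OE, a call that rested on single arrays. With the brightest probe set per gene, which for SPL4 is the _x_at one, none of the 6 measured members passed over all probe sets in limma, 1 had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. The mean log2 difference was -0.18 (camera adjusted p = 0.012). The call was lost with an estimated correlation (adjusted p = 0.657 with an estimated correlation; fry 0.185), without OE_L3 replicate 2 (0.0941) and without WT_L3 replicate 1 (0.389). Without WT_L3 replicate 1 the mean was -0.0149. SPL4 and SPL12 (LOC4341986) led the list, SPL12 with 191 ± 50.1 against 240 ± 40.2. SPL2, SPL7, SPL14 and SPL16 had log2 differences of -0.25, -0.13, 0.06 and 0.03, and none passed. The 5 measured SPL genes without a site had a mean of 0.04 (camera adjusted p = 0.787). None of the 5 passed, adjusted over all probe sets or adjusted over the list alone. Their log2 differences were 0.15 for SPL1, -0.10 for SPL6, 0.25 for SPL8, -0.07 for SPL9 and 0.00 for SPL15. A further SPL6 probe set was at 271 ± 18.7 in OE_L3 against 296 ± 36.4 in WT_L3.

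Camera called 3 further lists in L3. All 3 calls were lost with an estimated correlation (adjusted p = 0.987 with an estimated correlation for chlorophyll synthesis and drought, 0.714 for nitrogen). Chlorophyll synthesis genes had a mean log2 difference of -0.07 over 15 members, with PORB, an enzyme that reduces protochlorophyllide, at 1797 ± 139 against 2170 ± 110 and CHLH, a magnesium chelatase subunit, at 613 ± 98.5 against 890 ± 77.2. Nitrogen assimilation and transport had a mean of -0.17 over 15 members, with the glutamine synthetase GLN1-1 at 1728 ± 258 against 2050 ± 261 and the nitrate reductase NIA1 at 310 ± 6.15 against 511 ± 183. Abscisic acid and drought genes had a mean of -0.52 and a median of -0.09 over 14 members, with the transcription factor genes DREB1G, at 47.3 ± 52.2 against 228 ± 42.9, and DREB1A, at 40 ± 19.9 against 131 ± 54.4. No member of these 3 lists passed in limma, over all probe sets or adjusted over the list alone, and 2, 0 and 5 had an unadjusted p under 0.05. Camera gave adjusted p = 0.0261, 0.00751 and 0.0105, and fry gave 0.753, 0.41 and 0.609. The chlorophyll call was lost without OE_L3 replicate 1 (0.0577), OE_L3 replicate 3 (0.301) or WT_L3 replicate 1 (0.659). The sign of the chlorophyll mean turned without OE_L3 replicate 3 (0.0251) and without WT_L3 replicate 1 (0.0470). The nitrogen call was lost without OE_L3 replicate 1 (0.412), where the mean was -0.0627, or WT_L3 replicate 2 (0.0561). The drought call was lost without OE_L3 replicate 2 (0.13), WT_L3 replicate 2 (0.115) or WT_L3 replicate 3 (0.0591) and with no filter (0.0873).

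In young leaves, the named genes that changed with over-expression were SPL4 and rab25, and both fell. SPL4 was at 211 ± 13.2 in OE_L6 and 364 ± 24.0 in WT_L6 on its _x_at probe set (1.68-fold, log2 -0.75, SE 0.10, limma adjusted p = 0.0195), and its _at probe set gave 76.1 ± 5.51 against 134 ± 8.47 (log2 -0.70, adjusted p = 0.00791). SPL12 was at 336 ± 13.1 against 585 ± 22.2 (log2 -0.77, adjusted p = 0.233), and SPL14 (LOC4345998), a regulator of plant architecture, at 65.1 ± 5.95 against 285 ± 173 (log2 -1.65, adjusted p = 0.568). Neither passed. SPL2, SPL7 and SPL16 had log2 differences of -0.28, -0.63 and -0.39 without passing, and a further SPL4 probe set had -0.32. With 1 array left out SPL7 ran from -0.86 to -0.23 and SPL2 from -0.45 to -0.16. SPL7 was at 68.0 in OE_L6 replicate 1, the array with the differing controls, and at 167 and 184 in replicates 2 and 3. The gene rab25 (LOC4326935) was at 39.7 ± 2.27 against 80.7 ± 6.53 (log2 -0.79, SE 0.08, adjusted p = 0.0021).

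**Figure D2:**
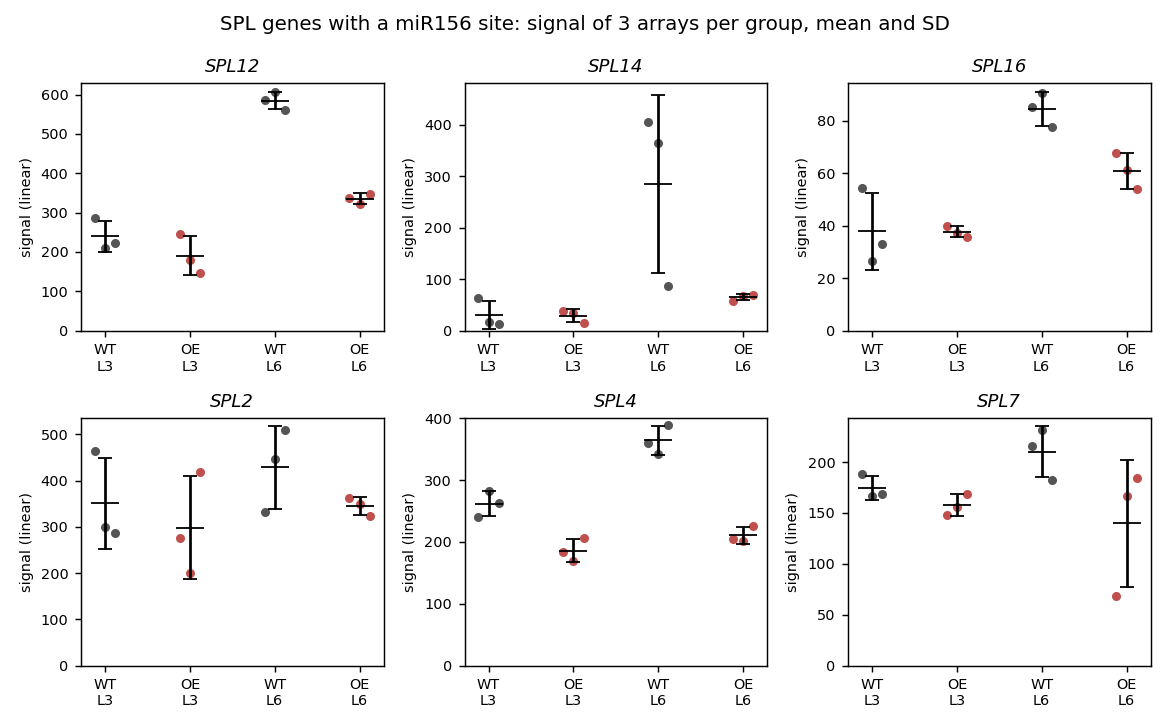
Linear signal (vertical axes, starting at 0) of the 6 measured SPL genes with a miR156 site, in the 4 groups (horizontal axes), with a point per array and the mean and SD in black. SPL12 lies at 336 ± 13.1 in OE_L6 and 585 ± 22.2 in WT_L6, and SPL4 at 211 ± 13.2 and 364 ± 24.0.

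As a set, the 6 SPL targets had a mean log2 difference of -0.74 in L6 (camera adjusted p = 3.46e-07). The set call was lost with an estimated correlation (adjusted p = 0.0823 with an estimated correlation). Of the 6, 1 was lower over all probe sets and 5 were lower adjusted over the list alone. Fry, which asks only whether the members move 1 way, gave adjusted p = 0.00204. The 5 SPL genes without a site had a mean of 0.06 (camera adjusted p = 0.954). None of these 5 passed, and their log2 differences were 0.27 for SPL1, 0.03 for SPL6, 0.16 for SPL8, -0.16 for SPL9 and -0.00 for SPL15. A further SPL6 probe set, outside the list test, went the other way, at 325 ± 17.2 in OE_L6 against 375 ± 13.6 in WT_L6. The call of SPL4 on its _x_at probe set was lost with quantile normalization (adjusted p = 0.103), with the 2 groups alone (0.0719), with 1 probe set per gene (0.0633) and without any 1 of the 6 L6 arrays (0.0506 to 0.116).

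Camera called 4 further lists as lower in OE_L6. All 4 calls were lost with an estimated correlation (adjusted p = 0.714 with an estimated correlation for flowering and drought, 0.657 for MADS-box and 0.987 for jasmonate). Flowering and phase regulators had a mean log2 difference of -0.31 over 6 genes and a MADS-box list one of -0.24 over 11, with MADS56 at 580 ± 108 against 1119 ± 50.5, MADS18 at 319 ± 47.2 against 662 ± 86.0 and MADS16 at 262 ± 17.5 against 487 ± 51.4. MADS genes encode transcription factors of flowering and floral organs, and some stand in both lists. Abscisic acid and drought genes had a mean of -0.66 and a median of -0.22 over 14 genes, with DREB1G at 21.6 ± 5.37 against 294 ± 259 and DREB1E at 108 ± 25.2 against 191 ± 52.5. With 1 array left out the mean of the drought list ran from -0.83 to -0.39. Jasmonate genes had a mean of -0.26 and a median of -0.08 over 26 genes, with the repressor genes JAZ13 at 38.1 ± 19.4 against 232 ± 151 and JAZ6 at 460 ± 123 against 682 ± 65.8. No member of these lists passed over all probe sets in limma. Those with an unadjusted p under 0.05 numbered 2 for flowering, 4 for MADS-box, 6 for drought and 1 for jasmonate, and adjusted over the list alone 2, 4 (1 higher and 3 lower), 2 and 0 passed.

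Camera gave adjusted p = 0.012 for flowering, 0.00751 for MADS-box, 0.00026 for drought and 0.0483 for jasmonate, and fry gave 0.0672, 0.023, 0.18 and 0.735. The flowering call was lost without OE_L6 replicate 2 (0.072), the MADS-box call with no filter (0.172), and the jasmonate call with no filter (0.0708), with a pseudocount of 64 (0.0537) and without any of OE_L6 replicates 1 (0.162) and 3 (0.131), WT_L6 replicates 1 (0.23) and 2 (0.0612) and WT_L3 replicates 2 (0.0508) and 3 (0.0612). Of all probe sets in L6, 35 changed, 24 higher and 11 lower, and 2650 had an unadjusted p under 0.05. The 2650 are more than the share of 0.05 that chance gives on average, though probe sets are not independent. All 35 had groups that did not overlap, as did 15.2% of all probe sets, where chance gives 10%. The count was 20 without OE_L6 replicate 1, the array with the differing controls, 21 without WT_L6 replicate 2 and 22 without WT_L6 replicate 3.

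The probe sets that rose with over-expression carried no gene name, and those described here were chosen after their values were seen. LOC4331398 was at 1201 in OE_L3 and 14.7 in WT_L3 on an _s_at probe set, for which paralogs are uncertain (log2 5.31, limma adjusted p = 1.7e-08), and at 309 in OE_L6 and 11.2 in WT_L6 (log2 3.56, adjusted p = 4e-07). Its second probe set gave log2 differences of 5.14 and 3.37. Its WT signal was at background, so the size of these differences depends on the pseudocount. A probe set with no gene in the annotation used was 4.62 higher in L3 and 4.65 higher in L6 on the log2 scale, and another 3.64 and 4.02. Of the 29 probe sets higher in L3 and the 24 higher in L6, 19 were shared, where independent lists would share 0.0203, and of the 12 and 11 lower, 4 were shared, against 0.00385. These comparisons share no array, but each leaf pair came from 1 plant. All OE plants were also transgenic and selected on hygromycin, so a shared rise need not follow from miR156. Of the called probe sets, 22 in L3 and 21 in L6 had no gene.

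The leaf comparison in WT asked which genes separate L6, a young leaf of a later position, from L3, an old leaf of an earlier one. The named genes with the largest falls from L3 to L6 were these. BURP17 (LOC4349896), of the BURP-domain family, was at 4004 ± 551 in WT_L3 and 19.6 ± 7.88 in WT_L6 (log2 -6.83, SE 0.43, limma adjusted p = 5.06e-06). The monosaccharide transporter MST3 fell from 2659 ± 391 to 80.2 ± 2.08, the lipoxygenase LOX2.1 from 1305 ± 249 to 23.7 ± 28.9, the chitinase Cht2 from 2618 ± 939 to 95 ± 89.2, the ammonium transporter AMT3-2 from 990 ± 180 to 20.9 ± 2.68 and AT5 from 1607 ± 143 to 30.4 ± 3.90. The L6 signals of BURP17, AMT3-2, LOX2.1 and AT5 were near background, so the size and rank of these falls depend on the pseudocount. The named genes with the largest rises were the laccases LAC7 (227 ± 325 to 2187 ± 260, log2 4.15, adjusted p = 0.00522) and LAC4 (108 ± 166 to 765 ± 39.9), CRSH2 (183 ± 230 to 1843 ± 302), TBL6 (266 ± 418 to 1421 ± 68.7), the homeobox gene HOS66 (164 ± 262 to 932 ± 286) and the cell-cycle inhibitor gene KRP6 (155 ± 243 to 884 ± 237). The last 6 had an SD above the mean in WT_L3, the group with the widest leaf-age scores. Cht2 and TBL6 probe sets end in _s_at and that of AMT3-2 in _x_at, so near-identical paralogs are uncertain, as for PORB, JAZ6, RPL27 and Cht3.

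Of 34316 probe sets, 16403 changed between the leaves of WT, 8193 higher and 8210 lower in L6, and 4944 of them by at least 2-fold. The groups did not overlap in 15255 of the called, and in 54.7% of all, where chance gives 10%. The count was 10665 without WT_L3 replicate 2 and 10305 without WT_L3 replicate 3. The calls of TBL6, HOS66 and KRP6 were lost without WT_L3 replicate 2 or 3 or WT_L6 replicate 2 or 3 (adjusted p 0.054 to 0.0939).

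Camera called 7 gene lists between the leaves of WT. All 7 calls were lost with an estimated correlation (adjusted p = 0.714 with an estimated correlation for pathogenesis-related genes and SPL targets, 0.987 for the others). Of all 15517 genes in the background 26.2% rose and 31.1% fell in L6. Of 13 measured pathogenesis-related genes, 12 fell in L6 (12 adjusted over the list alone, mean log2 -2.24), with a chitinase gene Cht1 (LOC4342115) at 565 ± 249 in WT_L3 and 30.0 ± 14.5 in WT_L6 and another gene of that name (LOC4338719) at 122 ± 10.5 and 11.9 ± 3.46. In the metal homeostasis list 16 of 28 fell and 2 rose (the same counts adjusted over the list alone), with MT1B at 759 ± 154 and 35.8 ± 2.30 and the zinc transporter ZIP2 at 349 ± 76.4 and 66.0 ± 4.45. Of 26 cell cycle and DNA replication genes, 14 rose (19 higher and 1 lower adjusted over the list alone), with the D-type cyclins CYCD3-1 at 124 ± 104 and 434 ± 55.8 and CYCD4-1 at 54 ± 55.7 and 295 ± 134. Of 39 cellulose and hemicellulose genes, 27 rose and 4 fell (28 and 5 adjusted over the list alone), and the 2 with the strongest statistic fell: CSLE1, from 968 ± 67.9 to 121 ± 28.1, and BC1L9, from 1158 ± 420 to 105 ± 53.8. Of 20 expansin genes, which loosen walls, 8 rose (7 adjusted over the list alone), with EXPA10 at 323 ± 98.4 and 597 ± 4.36 and EXPA16 at 67.8 ± 43.4 and 212 ± 23.8. Of 23 ribosomal protein genes, 4 rose (0 adjusted over the list alone, 6 with an unadjusted p under 0.05), a smaller share than of all genes, RPL27 from 2035 ± 234 to 2846 ± 377 and RPS26 from 1595 ± 321 to 2317 ± 243. SPL targets rose in 4 of 6 (4 adjusted over the list alone, mean log2 0.96), SPL12 from 240 ± 40.2 to 585 ± 22.2 and SPL16 from 37.9 ± 14.6 to 84.5 ± 6.56.

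Camera gave adjusted p = 0.000334 for pathogenesis-related genes, 0.0294 for metals, 0.00307 for cell cycle, 0.00691 for cellulose, 0.0483 for expansins, 0.0496 for ribosomal proteins and 0.046 for SPL targets. In the same order fry gave 0.000199, 0.00464, 0.108, 0.255, 0.136, 0.39 and 0.000894. The SPL call was lost without WT_L3 replicate 1 (0.0577), the ribosomal call without WT_L3 replicate 2 (0.214) or WT_L6 replicate 2 (0.128), and the expansin call without WT_L3 replicates 2 (0.0643) or 3 (0.0589), WT_L6 replicate 2 (0.0535) or OE_L6 replicate 2 (0.0517). With no filter the expansin (0.182), metal (0.113) and ribosomal (0.0554) calls were lost, the ribosomal call also with a pseudocount of 64 (0.0537). The calls of RPL27, RPS26 and CYCD4-1 were lost without 3 arrays each in turn, WT_L3 replicate 3 and WT_L6 replicate 2 among them (adjusted p 0.0501 to 0.0852). Markers of other tissue moved unevenly: of 6 meristem KNOX genes 2 rose and 3 fell (mean log2 0.48, median -0.06), of 7 pollen and anther genes 3 rose, of 4 seed storage genes 1 rose and 1 fell, and of 6 histone genes 1 rose.

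In the over-expression lines the same leaf comparison gave many of the same genes. The chitinase Cht11 was at 3181 ± 544 in OE_L3 and 62.2 ± 13 in OE_L6 (log2 -5.35, SE 0.48, limma adjusted p = 5.01e-05), and Cht2, BURP17, LOX2.1, MST3 and AMT3-2 fell too, with log2 differences of -5.28, -4.99, -4.72, -4.47 and -4.45. The OE_L6 signals of LOX2.1 and AMT3-2 were near background as well. Among the named genes, the largest rises were those of LAC7 (281 ± 231 to 1714 ± 411, log2 2.94, adjusted p = 0.0271), the cell-wall invertase gene CIN2 (79.3 ± 61.9 to 500 ± 59.2), LAC4 (115 ± 90.5 to 593 ± 12.5), the COBRA-like gene BC1 (LOC4333114, 146 ± 107 to 703 ± 78.1), CRSH2 (421 ± 293 to 1912 ± 262) and the cytokinin response regulator RR1 (101 ± 24.5 to 562 ± 131). Of 34316 probe sets, 14445 changed, 6478 higher and 7967 lower in L6. The calls of LAC4 and BC1 were lost with the plant as a block (adjusted p = 0.0512 and 0.055). Those of CIN2, LAC4 and BC1 were lost with the plant as a random block (0.0507, 0.0506 and 0.0633) and with a pseudocount of 1 (0.0724, 0.0654 and 0.0668), and that of BC1 with no filter (0.0574) and no trend (0.0513).

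The OE count was 8902 without OE_L3 replicate 3, and without that array the calls of LAC7, CIN2, LAC4, BC1 and CRSH2 were lost (adjusted p 0.101 to 0.183). They were lost too without any 1 of the OE_L6 arrays (0.0541 to 0.106), and those of LAC4 and BC1 without OE_L3 replicate 1 (0.0529 and 0.0569). The groups did not overlap in 14258 of the called probe sets and in 59.4% of all, where chance gives 10%.

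Camera called 7 lists between the leaves of OE, where 21.1% of the background genes rose and 29.4% fell in L6. With an estimated correlation all 7 calls were lost (adjusted p = 0.714 with an estimated correlation for pathogenesis-related genes, 0.987 for the others). SPL targets, called in WT, rose in 2 of 6 (2 adjusted over the list alone, camera adjusted p = 0.274) and were not called. In L6, 11 of 13 pathogenesis-related genes fell (12 adjusted over the list alone), with Cht3 at 202 ± 24.5 in OE_L3 and 25.2 ± 3.26 in OE_L6 and Cht1 (LOC4342115) at 659 ± 27.4 and 38.7 ± 9.68. Metal homeostasis genes fell in 13 and rose in 2 of 28 (14 and 3 adjusted over the list alone), with the metal-nicotianamine transporter gene YSL13 at 1546 ± 336 and 83.5 ± 41.8 and ZIP2 at 387 ± 29.6 and 66.8 ± 13.8. Chlorophyll synthesis genes rose in 11 of 15 (11 adjusted over the list alone; in WT 8 rose and 3 fell, camera adjusted p = 0.119, not called), with CHLG at 730 ± 84.8 and 1253 ± 120 and PPOX1 at 594 ± 125 and 1328 ± 59.4. Ribosomal protein genes rose in 9 of 23 (9 adjusted over the list alone), RPL27 from 2033 ± 234 to 2839 ± 286 and RPS26 from 1614 ± 293 to 2407 ± 238. Cell cycle genes rose in 7 and fell in 1 of 26 (0 adjusted over the list alone, 19 with an unadjusted p under 0.05), with CYCD3-1 at 109 ± 36.8 and 339 ± 51.8 and CYCD5-3 at 81.4 ± 9.99 and 108 ± 13.1. Cellulose and hemicellulose genes rose in 12 and fell in 4 of 39 (14 and 4 adjusted over the list alone), and CSLE1 and BC1L9 fell here too, from 812 ± 146 to 154 ± 34.1 and from 1549 ± 349 to 86.3 ± 25.7. Expansins rose in 7 and fell in 1 of 20 (the same counts adjusted over the list alone), with EXPB8 at 58.8 ± 1.39 and 84.7 ± 3.4 and EXPA16 at 69.5 ± 27.9 and 169 ± 16.6.

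Camera gave adjusted p = 0.00026 for pathogenesis-related genes, 0.0237 for metals, 0.0105 for chlorophyll synthesis, 0.00921 for ribosomal proteins, 0.00324 for cell cycle, 0.011 for cellulose and 0.035 for expansins. In the same order fry gave 0.000199, 0.0067, 0.0251, 0.204, 0.144, 0.426 and 0.144. The expansin call was lost without OE_L3 replicate 3 (0.0726) or OE_L6 replicate 3 (0.0582) and with no filter (0.078). Without OE_L3 replicate 3 the calls of RPL27, RPS26, CYCD3-1, CYCD5-3 and EXPA16 were lost (0.0587 to 0.0761), and without OE_L6 replicate 2 those of RPL27, RPS26 and CYCD5-3 (0.0597 to 0.0657). Without OE_L6 replicate 1 those of CYCD5-3 (0.0612) and EXPA16 (0.05) were lost, and with only the groups compared that of CYCD5-3 (0.0557). In OE, 1 KNOX gene rose and 2 fell of 6, 3 of 7 pollen and anther genes rose, 1 of 4 seed storage genes fell and 1 of 6 histone genes rose.

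The leaf differences of WT and OE were close to each other across probe sets. Their correlation was 0.966 and their covariance 0.640, where unchanged groups gave -0.00118 on average, and these comparisons share no array. Of the probe sets called in WT, 99.2% had the same sign in OE, and of all probe sets 87.7%. Calls higher in L6 in both genotypes numbered 5411, where independent lists would share 1547, and calls lower in both 6804, against 1906. The variance of the leaf difference, less that of the residual spread, was 0.684 in WT and 0.526 in OE, a log2 ratio of -0.38. An exact permutation of plants between genotypes gave two-sided p = 0.8 for this ratio, and the smallest p that 10 exchanges can give is 0.1. Without WT_L3 replicate 2 the ratio was 0.0034 and without WT_L3 replicate 1 it was -0.94.

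Over-expression and leaf age were also set against each other. In L6 the covariance of the OE difference with the WT leaf difference was -0.0467, where unchanged groups with the shared WT_L6 arrays gave -0.0143 on average (-0.0434 to 0.00414 in 95% of 1000 draws), and the correlation was -0.25 against a simulated -0.36. In L3 the covariance was 0.0596 against a simulated 0.0488 (-0.0195 to 0.209), and the correlation 0.33 against 0.52. The L3 covariance lay inside the simulated range and the L6 covariance just outside it. The simulated arrays held no leaf difference, so the simulated correlations cannot be compared with the observed ones. The simulated covariance ranges also leave out spread of arrays along the real leaf difference, and may be too narrow. The L6 covariance outside its range thus does not show an effect. The simulated mean already holds the covariance from the shared controls, which 3 WT arrays estimate only roughly. Less the covariance of the shared arrays, the L6 value was -0.0318, and 9.12e-05 without WT_L6 replicate 2.

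The leaf difference itself differed between genotypes for 3 probe sets, and 844 had an unadjusted p under 0.05. The 844 are fewer than the share of 0.05 that chance gives on average. A probe set with no gene in the annotation used rose from 15.8 to 187 in WT but went from 19 to 37.4 in OE (log2 -2.08, SE 0.19, limma adjusted p = 0.0184). LOC4331398 was higher in OE_L3 than in OE_L6 and low in both WT leaves (log2 -1.75 and -1.77 on its probe sets, adjusted p = 0.0275 and 0.0345). All 3 lay outside the rule for named genes and were chosen after their values were seen. With the plant as a block none of the 3 passed (adjusted p = 0.291 for the probe set with no gene, 0.291 and 0.23 for LOC4331398). Then 596 probe sets had an unadjusted p under 0.05, again fewer than chance gives on average. The count was 0 without OE_L3 replicate 2, without OE_L6 replicate 1 and without any 1 WT_L6 array, 1 without WT_L3 replicate 2 or 3, and 7 without OE_L3 replicate 3. The groups' plant differences did not overlap for 5.64% of probe sets, where chance gives 10%.

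The SPL targets had a mean interaction of -0.56 on the log2 scale, that is, a smaller rise from L3 to L6 in OE (camera adjusted p = 0.00173, and adjusted p = 0.436 with an estimated correlation; fry 0.0929). No member passed in limma, over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The strongest statistics were those of SPL14 at -1.71 (SE 0.75) and SPL4 at -0.28 (SE 0.14) on its _x_at probe set, with SPL7, SPL12, SPL16 and SPL2 at -0.50, -0.45, -0.42 and -0.03. Chlorophyll synthesis had a mean of 0.13 (camera adjusted p = 0.0217, and 0.987 as adjusted p with an estimated correlation; fry 0.735), with CHLH at 0.50 and CHLI at 0.30, with 0 members passing over all probe sets or adjusted over the list alone and 0 with an unadjusted p under 0.05. That call was lost without OE_L3 replicate 3 (0.206), OE_L6 replicate 2 (0.192), WT_L3 replicate 1 (0.444) or WT_L6 replicate 1 (0.362).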

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

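The tests of genotype exchange, of the leaf 3 gap, of RNA quality and of the splits in L3 were chosen only after the result was seen, as was the leaf-age covariate.

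Array controls outside the comparisons differed between genotypes. Reporter control probe set RPTR-Os-K01193-1_at was at 3541 ± 1332 in OE and 18.7 ± 5.74 in WT (n = 6 arrays each), and RPTR-Os-A00196-1_s_at at 2578 ± 551 and 45.9 ± 11.3. The ratios of these linear means, without a pseudocount, were 189 and 56.1, and since WT was at background they are no exact folds. All 6 OE arrays lay above all 6 WT arrays in both. Which sequences these probe sets read is not given in the sources used here. The OE plants alone were transgenic and selected on hygromycin, so construct sequences differ between the genotypes by design. Whether both probe sets read such sequences was not tested. Ribosomal RNA controls went the other way: 5.8S was at 30.2 to 45.9 in OE and 50.1 to 89.6 in WT, with no overlap. Of the 18S probe sets, 1 was at 117 to 743 in OE and 744 to 1024 in WT. Its ranges all but touched, at 743.447 and 743.575. The array with the differing controls, OE_L6 replicate 1, had the lowest mean 18S signal (225). The ranges of the other 18S, the 25S and the 28S probe sets overlapped. A difference in RNA preparation between genotypes is thus left open and was not tested.

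The leaf difference differed between genotypes for 3 probe sets by the interaction test. These were the 2 probe sets of LOC4331398 (log2 -1.75 and -1.77) and a probe set without a gene (log2 -2.08). With the plant as a block none of the 3 passed in limma. Then 596 probe sets had an unadjusted p under 0.05, fewer than chance gives on average. The highest count among the other 9 exchanges of plants was 2746, against 3 for the real one, which 3 of 10 exchanges reached. The 10 exchanges are too few for a share under 0.05.

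The L3 arrays were spread along the leaf-age axis, and this pattern was weighed against technical explanations. An exchange of genotype labels among L3 arrays has a value against it: with reporter probe sets and thresholds taken from L6 arrays, 0 of 6 L3 arrays lay on the other genotype's side. That test leaves out dim reporters, a filter applied after a first result was seen, in which 1 very dim reporter (signals of 0.185 to 4.47) put 1 of 6 L3 arrays on the other side; an exchange would need a partner out of place as well. A young leaf labelled as old has a value against it too, since the gap between the highest L3 score (0.382) and the lowest L6 score (0.878) was 0.496, larger than the L6 range of 0.230. RNA quality stays open. The range of the actin 3′ to 5′ log2 ratio was 1.05 in L3 against 0.667 in L6, while for GAPDH it was 0.450 against 0.465. The GAPDH probe sets used were dim, with mean 3′ and 5′ signals of 44.7 and 18.7 in OE and 44.8 and 20.1 in WT. A brighter GAPDH pair on the array (3′ mean 5279 in OE) was not used. The GAPDH range thus cannot speak for or against RNA quality. Differences in how far the old leaves had aged may underlie the spread and were not tested.

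The low count between genotypes in L3 was weighed against that spread. With the leaf-age score as a covariate 84 probe sets passed, against 41 without it. The score came from the same arrays and probe sets. A rise could follow from that alone, so whether the spread hid part of the genotype difference stays open. In the splits of the 6 L3 arrays, 2 of 10 called as many as the real 41, and the highest other called 4392. That split set WT_L3 replicate 1 with OE_L3 replicates 1 and 2, the arrays with the highest leaf-age scores, which points to a structure of the samples other than genotype. In L6, 2 of 10 splits called as many as the real 35, and the highest other called 146, with WT_L6 replicate 1 beside OE_L6 replicates 1 and 3, again a structure of the samples. Between the leaves, the real split called 16403 in WT and 14445 in OE, the highest other called 0 in each, and 1 of 10 reached the real count. With 10 splits no share can fall under 0.05.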

How the results depend on the processing

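The leaf-age covariate was chosen only after the result was seen; the other alternatives were planned.

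The counts between leaves were 16403 in WT and 14445 in OE. They were 9181 and 8175 with 1 probe set per gene and 4944 and 3783 with a 2-fold minimum, which by construction test or call fewer. Leaving out 1 replicate in turn gave 10305 to 18399 in WT and 8902 to 12562 in OE. The lowest values came without WT_L3 replicate 3 (10305; 10665 without replicate 2) and without OE_L3 replicate 3 (8902).

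The count in L3, 41 as planned, was 62 with no filter, 25 with the 60th percentile filter, 12 with only the groups compared, 4 with 1 probe set per gene, 23 with a 2-fold minimum and 84 with the covariate. Leaving out 1 replicate gave 22 to 48, with 25 without OE_L3 replicate 1 and 22 without OE_L3 replicate 2 or WT_L3 replicate 2. The count in L6, 35 as planned, was 22 with the 60th percentile filter, 2 with 1 probe set per gene and 66 with the covariate. Leaving out 1 replicate gave 20 to 45, with 20 without OE_L6 replicate 1, 21 without WT_L6 replicate 2 and 22 without WT_L6 replicate 3. The interaction count, 3 as planned, was 0 with a pseudocount of 1, 6 with 64, 7 with no filter, 1 with the plant as a random block, 1 with 1 probe set per gene and 8 with the covariate, and 0 to 7 with 1 replicate left out. Apart from fewer probe sets or arrays, the cause was not tested.

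With the replicate number as a block, which pairs the leaves of a plant in the leaf comparisons and the interaction, the interaction count was 0, the calls of LAC4 (adjusted p = 0.0512) and BC1 (0.055) in the leaf comparison of OE were lost, and the 3 interaction probe sets did not pass. Between genotypes the replicates share only a number, and there the block gave adjusted p = 0.0961 for NMCP1A in L3 and 0.0515 for the jasmonate list in L6. Deviations of OE and WT arrays with the same number correlated at 0.730, -0.724 and 0.802 in L3. The other called lists, and the other called genes of the rule for named genes, kept their calls; the unnamed probe sets between genotypes and the _at probe set of SPL4 in L6 were not followed one by one. With the block 28 list tests passed against 25, and of the probe sets called as planned 28 of 41 in L3, 29 of 35 in L6, 13059 of 16403 in WT and 10855 of 14445 in OE were called again.

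With an estimated correlation 0 of the 170 list tests passed, against 25, and the cause of this loss was not tested. Leaving out 1 replicate gave 24 to 31.

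The correlation of the leaf differences, 0.966 as planned, ran from 0.926 to 0.970 with 1 replicate left out. The size ratio, -0.38 on the log2 scale, ran from -0.94 to 0.0034, so its sign turned without WT_L3 replicate 2. The covariance with over-expression in L6, -0.0318, ran from -0.0772 to 9.12e-05, and in L3, 0.0121, from -0.0942 to 0.242, negative without OE_L3 replicate 1 or 2 or WT_L3 replicate 2 or 3. The cause was not tested.

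Signs turned for SPL genes with differences near 0, none of which passed. In L3, SPL15 was at -0.0117 with quantile normalization and -0.0416 with the covariate, SPL16 at -0.0630 and SPL14 at -0.16 with the covariate. With 1 replicate left out SPL15 ran from -0.0456 to 0.0669, SPL16 from -0.13 to 0.24, SPL14 from -0.22 to 0.51 and SPL1 from -0.12 to 0.31. In L6, SPL15 was at 0.0282 with the covariate and ran from -0.0329 to 0.0157 with 1 replicate left out, and SPL6 from -0.0224 to 0.112.

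Of 26 named genes called between leaves, 20 passed in every alternative in WT and 16 of 26 in OE. In L6, rab25 passed in every alternative run (adjusted p 0.000937 to 0.0259). In L6 the covariate added calls for SPL12 (0.0446), MADS56 (0.0111), MADS18 (0.0213) and MADS16 (0.0105), and SPL12 also passed with only the groups compared (0.0428). MADS16 also passed with quantile normalization (0.0122) and a pseudocount of 64 (0.0379). Signal near the background limits what can be seen for dim probe sets, and the filter leaves many of them untested.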

Other observations

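The gene groups below were planned lists with planned tests, and those told of here were chosen after their values were seen.

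Some lists that camera did not call had most of their members falling in L6. Clock genes fell in L6 in 6 of 7 in WT and 5 of 7 in OE, NAC genes in 5 of 6 and 4 of 6, and WRKY genes in 4 of 5 and 3 of 5. Camera gave adjusted p = 0.0766 and 0.0954 for clock genes, 0.127 and 0.0961 for NAC and 0.211 and 0.182 for WRKY, and fry gave 0.0175 and 0.0197, 0.0181 and 0.0181, and 0.023 and 0.0203. Fry asks whether the members move 1 way, whereas camera sets them against all other genes, of which 31.1% fell in WT and 29.4% in OE. Of 36 heat shock protein genes, 4 rose and 13 fell in WT, and 2 rose and 12 fell in OE (camera adjusted p = 0.332 and 0.277, fry 0.0197 and 0.0176). Of 26 jasmonate genes, 1 rose and 7 fell in WT, and 0 rose and 11 fell in OE (camera adjusted p = 0.395 and 0.0535, fry 0.0349 and 0.0175), and 12 of these 26 had an unadjusted p under 0.05 in OE.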
